A study of Mus musculus with 8 samples.

How the data were processed

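Expression was measured in 2 kinds of cell captured with a laser from frozen sections of the mouse yolk sac at embryonic day 9.5: primitive erythroid precursors, the red cell precursors made in the yolk sac, and epithelial cells. The mice were of the inbred strain FVB/N. There were 8 samples, 4 erythroid and 4 epithelial, in 4 pairs. Per the labels' protocols, the epithelial cells of a pair came from the slides that had given its erythroid cells, 2 to 4 yolk sacs from 2 litters went into each replicate, and 10 to 39 ng of RNA was amplified in a two-cycle labelling protocol. An erythroid cell was captured with 2 to 3 laser pulses and an epithelial cell with 1. Each sample was hybridised to its own Affymetrix Mouse Genome 430A 2.0 array.

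The authors deposited 1 value per probe set and array, an intensity (MAS5 signal) on a linear scale. The submitters' processing notes name GCOS, MAS5 and affy, and their versions are not given in the sources used here. In the deposited table, the mean intensity after trimming 2% at each end was 500 on each of the 8 arrays. Detection calls were not used here. The table held 22690 probe sets, of which 64 were the array maker's controls. Of the other 22626 probe sets, 20380 were annotated to 1 gene, 691 to several genes and 1555 to none here. Symbols were brought up to date through gene identifiers for 20351 probe sets. No gene was named from a probe set annotated to several genes, which left out the adult alpha globins and the jointly annotated adult beta globins.

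The following choices were made before the data were examined: the test, the scaling rule, the filter, the gene lists, the background level, the alternatives and the rule for named genes. An offset of 8.14, the 10th percentile of all deposited values, was added to each value before log2 was taken. The medians of the 8 arrays then spanned 0.59 on the log2 scale, above the limit of 0.5 set for the use of deposited scaling, so the arrays were quantile normalised. A probe set was tested if it reached its array's median on at least 4 of the 8 arrays, which left 11449 probe sets and 7191 genes. The fit was made in R 4.3.3 with limma 3.58.1 (lmFit and eBayes with a variance trend), with terms for the pair and the cell type and 3 residual degrees of freedom. Tests were two-sided, with Benjamini-Hochberg adjustment over all probe sets tested and a threshold of 0.05. Log2 fold changes are erythroid minus epithelial and carry the standard error (SE) of the fit. Mean signals are means of 4 deposited values. A gene was read from its tested probe set with the highest mean over all arrays.

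The pairing was checked on the tested probe sets. The deviations of the 2 samples of a pair from their group means correlated at 0.44, 0.34, 0.31 and 0.54 in pairs 1 to 4. The pairing itself comes from the labels' protocols. In the erythroid and epithelial samples of different pairs, the correlations lay between 0.28 and 0.35 within pairs 1 and 2 and within pairs 3 and 4, and between -0.45 and -0.29 across these sets.

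Of 27 gene lists, 26 were tested with camera (limma) at a preset inter-gene correlation of 0.01, with adjustment over the lists, on 1 probe set per gene. The list of sex-linked genes served only to check the pairing. Each list also has a count of calls adjusted over the list alone, a camera test with the correlation estimated from the data, and fry tests in 1 direction and in either direction. Across the lists, 4 tested members stood in more than 1 list. The background level of an array was the 95th percentile of 117 probe sets for odorant, pheromone and taste receptors, keratin-associated proteins and beta-defensins. No gene named below lay under that level on all arrays of a group. The ratio of 3' to 5' signal of the maker's Gapdh and Actb controls was compared between cell types within pairs by a two-sided exact sign-flip test, which 4 pairs are too few to take below the threshold.

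Genes were named by rule: the 12 with the largest change in each direction among calls with 1 sign in all 4 pairs, the 3 members of each list with the largest change and the 1 with the smallest, and 14 genes fixed in advance. Not every gene that the rule allows is printed. Outside the rule, Mpp1, Igf2, Sox17, Cited2, Cdc6, Rfc4, Klf10, Btg1, Slc2a3, Rab27b, Fli1, Atp5a1, Top2a, Creb3l3, Nr2f6, Gstm1, Glrx, Rhag, Vim, Col3a1, Acta2, Ahnak, Postn, Apoe and Fgb were chosen after their values were seen, most of them to name the members behind a small count.

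The procedure was tested on simulated data for this comparison, with 200 of the 11449 probe sets changed in each of 5 runs. It called 55.5% of those changed by a log2 value of 2, 11.3% of those changed by 1 and 1.79% of those changed by 0.5, and 1.73% of its calls were false. In the data 13.9% of the probe sets tested were called, a far larger share than was changed in the simulation. The adjustment depends on that share, so these percentages need not hold for the data. The procedure called 15 of 15 lists shifted by 0.5 and 0 of 115 lists that were not shifted. The simulated probe sets varied independently of each other, so the list result does not cover lists whose members vary together. In the data the estimated correlation reached 0.49, in the mesenchyme list. The alternatives were no pair term, other offsets, other scalings, other filters, other variance models, fewer kinds of probe set, each pair left out, other set tests, the mean of a gene's probe sets and a 2-fold minimum. The separate fits of pairs 1 and 2 and of pairs 3 and 4 were chosen after seeing the data. Each rests on 2 pairs and has fewer residual degrees of freedom than the 3 of the main fit. Their p-values therefore rest mostly on the variance shared across probe sets, and their calls are not on a par with the main ones. Fits on fewer pairs were normalised and filtered anew, and the probe set of each list member was chosen anew. The members of a list can therefore differ, and its median over all 4 pairs need not lie between those of the 2 sets.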

Results

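The data were 8 arrays, 1 for each of 4 erythroid and 4 epithelial captures from the yolk sac of the mouse at embryonic day 9.5. The median signal of an array lay between 81.6 and 127, and the highest between 24644.6 and 58408.3. Between 48.7% and 57.7% of the probe sets on an array lay above its background level. The number of arrays, 4 in each group, limits the precision of each value. The ratio of 3' to 5' signal of the Gapdh control, a sign of shortened RNA, was 38.7 to 44.4 on the 4 arrays of pairs 1 and 2, and 7.0 to 17.4 on those of pairs 3 and 4. The Actb control gave 46.5 to 131 and 7.75 to 13.5. Because these ratios part pairs 1 and 2 from pairs 3 and 4, medians within each set stand beside those of each list called, and values within each set beside some genes. Between the cell types the ratios differed by less than their spread: the mean log2 difference was 0.28 for Gapdh (SD 0.56, n = 4 pairs, exact p = 0.5) and -0.21 for Actb (SD 0.95, n = 4 pairs, exact p = 0.75).

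The comparison asked which genes erythroid precursors express more than the epithelial cells of the same yolk sacs. Red cell lists called higher in the erythroid captures with camera were those of transcription factors, heme synthesis, the membrane and erythropoietin signalling. Those of globins, antioxidant defence and maturation were not called, and with an estimated correlation no list was. Klf1, a transcription factor of red cells, was higher by 2.49 ± 0.30 on the log2 scale (SE, n = 4 pairs), at mean signals of 2571 and 413. Slc4a1, the anion exchanger of the red cell membrane, was higher by 2.32 ± 0.34, and the embryonic alpha-like globin Hba-x by 1.66 ± 0.16. Genes of the visceral endoderm, the epithelium that makes serum proteins and takes up nutrients for the embryo, were lower: Apoa1, the main protein of high-density lipoprotein, fell by 1.22 ± 0.10, the uptake receptor Cubn by 1.35 ± 0.14 and Vil1, a protein of microvilli, by 1.83 ± 0.21. Each of these 6 genes had 1 direction in all 4 pairs.

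Of 11449 probe sets tested with limma, 709 were higher and 881 lower in the erythroid captures, and 396 and 580 of these differed at least 2-fold. All 1590 had the same sign in the means of pairs 1 and 2 and of pairs 3 and 4, and 1568 had 1 sign in all 4 pairs. Selection by a fit of these same pairs favours a common sign, so this agreement is no separate support. At the level of genes, 433 of 7191 were higher and 638 lower. Of the probe set calls, 44.6% were higher in the erythroid captures, against 29.3% (455 higher, 1097 lower) with the arrays centred on their medians, a scaling that moved the median of all tested probe sets from 0.02 to -0.11. The calls were fewer without the pair term (160 higher, 285 lower), without a variance trend (179 and 339), without replicate 3 (318 and 461) and without replicate 4 (214 and 342). Fits of pairs 1 and 2 alone gave 480 higher and 544 lower, and fits of pairs 3 and 4 alone 1379 and 1445. With 2 pairs each, these counts cannot be set directly against those of all 4 pairs.

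The difference between captures was smaller in pairs 1 and 2. Among the 1590 probe sets called, 1359 differed more in pairs 3 and 4, and the median ratio of the change in pairs 1 and 2 to that in pairs 3 and 4 was 0.601. A test of this interaction called 211 probe sets, and 1530 at an unadjusted p under 0.05. Klf1 was higher by 1.78 in pairs 1 and 2 and by 3.11 in pairs 3 and 4 (adjusted p of the interaction 0.0474), and Slc4a1 by 1.40 and 3.14 (0.00141). Of the genes named below, Upk3b was at 0.34 and 3.10 (0.00788), Rps15 at 0.29 and 1.33 (0.00822) and Apoe at -0.83 and -2.50 (0.00999), with no call in pairs 1 and 2 alone. Blvrb, Slc25a37, Rhag, Pf4, Fabp1, Car2, Kcnn4, Serpinf2, Fgb and Idi1 also differed more in pairs 3 and 4 (adjusted p of the interaction 0.00823 to 0.0415).

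Transcription factors of red cells were higher in the erythroid captures. Of 17 tested, 9 rose and 0 fell (10 and 0 adjusted over the list alone), with a median of 1.12 on the log2 scale (camera adjusted p = 3.2e-05; adjusted p = 0.307 with an estimated correlation). With the directional fry test this list was not called (adjusted p = 0.0754), nor were 6 of the other lists called higher here, those of the red cell membrane, erythropoietin, mesenchyme, platelets, endothelium and DNA replication (0.0754 to 0.139). Beside Klf1, these included Tal1 at 2.12 ± 0.39 and Gata1, a regulator of globin and heme genes, at 2.05 ± 0.32 (mean signals 1238 and 273). Tal1 and Gata1 were higher in 4 of 4 pairs. The list's median was 0.70 in pairs 1 and 2 and 1.60 in pairs 3 and 4.

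Heme synthesis and iron uptake rose with them: 12 of 19 genes were higher and 0 lower (12 and 1 adjusted over the list alone), at a median of 1.27 (camera adjusted p = 1.72e-06; adjusted p = 0.307 with an estimated correlation). The medians were 0.75 in pairs 1 and 2 and 1.60 in pairs 3 and 4. The transferrin receptor Tfrc was higher by 1.59 ± 0.28 and the mitochondrial iron importer Slc25a37 by 2.04 ± 0.31. Tfr2 was higher by 2.05 ± 0.43, and the mean of its tested probe sets gave 1.26 (adjusted p = 0.205). Alas2, the enzyme that starts heme synthesis in red cells, was higher by 1.98 ± 0.52, at 0.48 in pairs 1 and 2 and 3.34 in pairs 3 and 4, and the interaction passed its test (adjusted p = 0.00256). The call of Alas2 ended without the pair term (adjusted p = 0.194), without replicate 3 (0.105) and without replicate 4 (0.151), and that of Tfr2 without replicate 3 (0.0567) and without replicate 4 (0.0721).

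Genes of the red cell membrane and blood groups gave 9 of 18 higher and 1 lower (13 and 1 adjusted over the list alone), with a median of 1.32 (camera adjusted p = 2.45e-06; adjusted p = 0.307 with an estimated correlation). Ermap, an erythroblast membrane protein, was higher by 2.49 ± 0.40, Epb42 by 2.46 ± 0.41 and the Rh-associated glycoprotein Rhag by 2.16. The member that fell was Mpp1, by 1.05, with no call without replicate 3 (adjusted p = 0.0763) or without replicate 4 (0.103). The medians were 0.49 in pairs 1 and 2 and 2.04 in pairs 3 and 4.

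The globin list did not pass as a set: 2 of 4 tested genes were higher and 0 lower, with the same counts adjusted over the list alone (median 0.86, camera adjusted p = 0.0583; adjusted p = 0.307 with an estimated correlation). It passed with the deposited scaling and with arrays centred on the median or the 75th percentile (adjusted p = 0.0129 to 0.0248), without replicate 1 (0.0488) and without replicate 4 (0.0477), and its adjusted p ran from 0.0099 to 0.307 over all alternatives. Hba-x was higher in 4 of 4 pairs, by 1.41 in pairs 1 and 2 and 1.89 in pairs 3 and 4. The embryonic beta-like globins did not pass, with Hbb-bh1 at -0.11 ± 0.07 and mean signals of 39902 in erythroid and 36732 in epithelial captures, and Hbb-y at 0.07 ± 0.07 with 35217 and 30017. A less bright probe set of Hbb-y gave 0.54 ± 0.13 (adjusted p = 0.0238). The 20 brightest probe sets on the arrays differed by at most 0.11 between cell types, and 0 were called. They were ranked by their mean over both cell types after quantile normalisation, which leaves little room for a difference. Hbb-b2 gave 3.04 ± 0.37 on a probe set of a kind that can pick up related transcripts, and 0.35 ± 0.49 (adjusted p = 0.683) on its other tested probe set, so its value is uncertain.

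**Figure D1:**
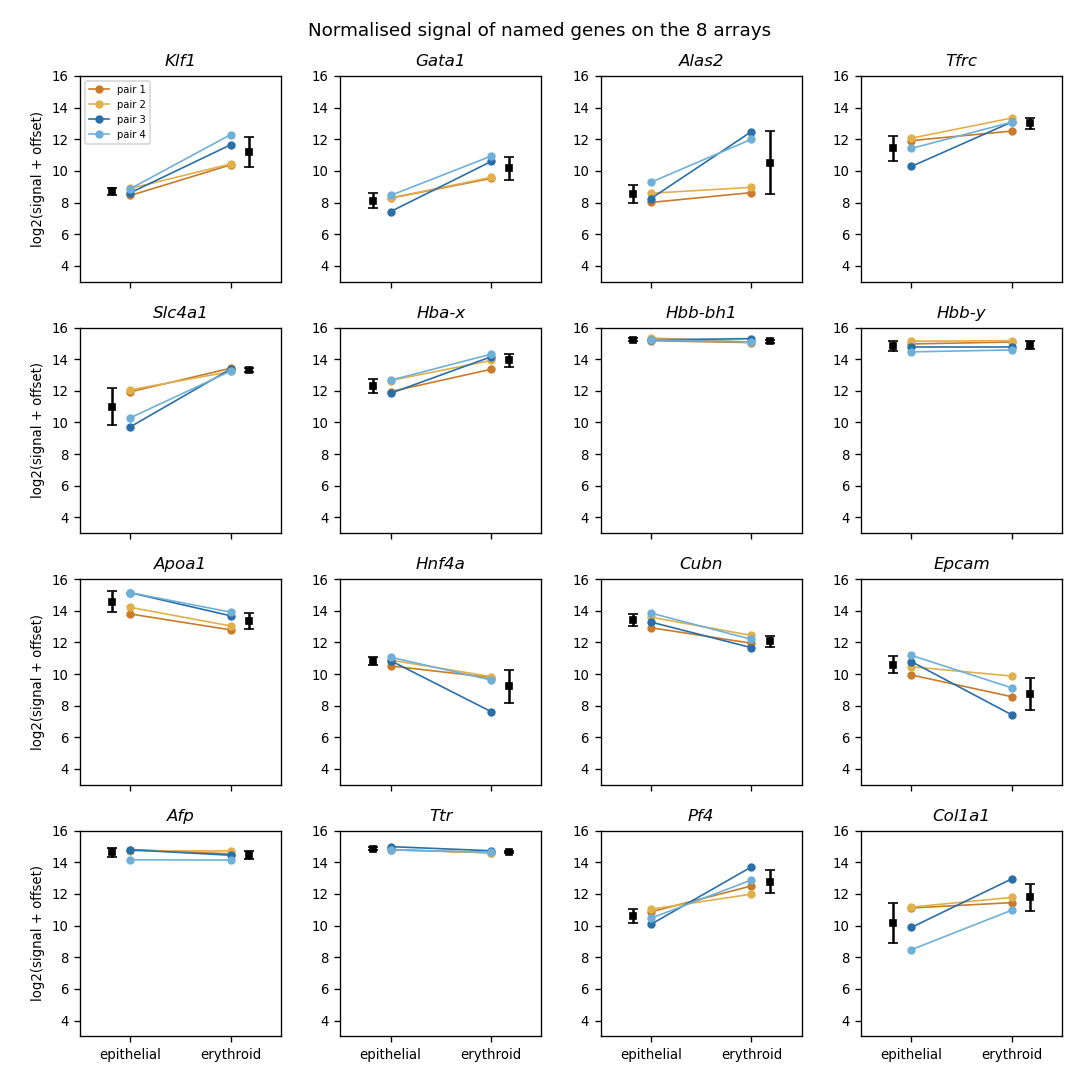
Normalised signal, as log2 of signal plus offset, of 16 genes on the 8 arrays. Each line joins the epithelial and the erythroid capture of a pair, and black squares with bars give the mean and SD of 4 arrays. Klf1, Gata1 and Slc4a1 lay higher in the erythroid capture of all 4 pairs and Apoa1 and Cubn lower, while Hbb-bh1 (-0.11 ± 0.07) and Hbb-y (0.07 ± 0.07) were nearly level.

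Other red cell lists moved less or in part. Of 14 genes of erythropoietin signalling, only Btg1, an inhibitor of proliferation, rose, by 0.82 (1 of 14 also adjusted over the list alone; median 0.54, camera adjusted p = 0.0097; adjusted p = 0.307 with an estimated correlation). The call of Btg1 ended without replicate 3 (adjusted p = 0.0549), without replicate 4 (0.0842), in pairs 1 and 2 (0.0618) and with median centring (0.0932), where 0 genes of the list were called. The receptor Epor was at 1.46 ± 0.58 (adjusted p = 0.117), at 0.23 in pairs 1 and 2 and 2.81 in pairs 3 and 4. The list's median was 0.20 in pairs 1 and 2, where it was not called (adjusted p = 0.216), and 1.02 in pairs 3 and 4.

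Red cell antioxidant genes split, with 7 of 17 higher and 2 lower (7 and 3 adjusted over the list alone). The list did not pass (median 0.06, camera adjusted p = 0.105; adjusted p = 0.307 with an estimated correlation), though it did without the pair term (0.0222) and in pairs 1 and 2 (0.0247), within a range of 0.00725 to 0.368 over all alternatives, and its median was -0.12 with the arrays centred on their medians. Blvrb, which reduces biliverdin, was higher by 2.24 ± 0.38, carbonic anhydrase Car2 by 1.98 ± 0.22 and Gclm, a subunit of the enzyme that starts glutathione synthesis, by 1.79 ± 0.20. Gstm1, a glutathione transferase, fell by 1.78 and Glrx by 0.70. The call of Glrx ended without replicate 1 (adjusted p = 0.0991), without replicate 3 (0.16) and without replicate 4 (0.182).

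Among 12 genes of maturation and protein turnover, 2 rose, Trim10 by 2.06 ± 0.32 and the ubiquitin ligase Mkrn1 by 1.38 ± 0.22, and 0 fell (3 and 4 adjusted over the list alone; median 0.07 and -0.10 with median centring, camera adjusted p = 0.795). Of 13 Kruppel-like factors, Klf1 rose, Klf9 fell by 1.36 and Klf10 by 0.70 (1 higher and 2 lower adjusted over the list alone; median -0.25, camera adjusted p = 0.765). The call of Klf10 ended when any of the 4 pairs was left out, at adjusted p = 0.0825 to 0.212. Klf2 was measured but its probe set was too dim to be tested.

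Genes of the endoderm were lower in the erythroid captures. Of 19 apolipoprotein and lipoprotein assembly genes, 14 fell and 0 rose (16 and 0 adjusted over the list alone), with a median of -1.27 (camera adjusted p = 1.84e-08; adjusted p = 0.307 with an estimated correlation). Apoa5 fell by 2.63 ± 0.49, the fatty acid binding protein Fabp1 by 2.05 ± 0.26, Mttp, which loads lipid onto apolipoprotein B, by 1.82 ± 0.30 and Apoe by 1.75, whose call ended without replicate 4 (adjusted p = 0.0581). The medians were -1.02 in pairs 1 and 2 and -1.56 in pairs 3 and 4.

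Of 20 secreted serum proteins, 13 fell and 1 rose (17 and 1 adjusted over the list alone), with a median of -1.43 (camera adjusted p = 9.71e-08; adjusted p = 0.307 with an estimated correlation) and medians of -0.99 in pairs 1 and 2 and -1.72 in pairs 3 and 4. Ambp fell by 2.25 ± 0.41, the plasmin inhibitor Serpinf2 by 2.23 ± 0.38, Serpina1b by 2.13 ± 0.27 and the fibrinogen chain Fgb by 2.01. The member that rose was the growth factor Igf2, by 0.75, with no call without replicate 4 (adjusted p = 0.11) or with median centring (0.164). The brightest probe sets of Afp and Ttr, a fetal and an adult carrier protein of serum, gave -0.16 ± 0.09 and -0.20 ± 0.07 (adjusted p = 0.249 and 0.0829), at mean signals of 26340 and 28477 in the erythroid captures. Of the other tested probe sets, 1 of 3 for Afp and 2 of 2 for Ttr were called, and these were lower, with the mean over all of a gene's tested probe sets at -0.43 for Afp (adjusted p = 0.0264) and -0.70 for Ttr (0.00319).

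Endocytic receptors and lysosomal genes followed, with 21 of 33 lower and 0 higher (24 and 0 adjusted over the list alone), at a median of -0.77 (camera adjusted p = 1.84e-08; adjusted p = 0.307 with an estimated correlation). Beside Cubn, the cholesterol transporter Npc1 fell by 1.83 ± 0.36 and the lysosomal protease Ctsh by 1.59 ± 0.19. Of 29 genes of epithelial junctions and keratins, 16 fell and 0 rose (20 and 1 adjusted over the list alone), at a median of -0.84 (camera adjusted p = 1.88e-07; adjusted p = 0.307 with an estimated correlation). The claudin Cldn7 fell by 1.85 ± 0.29 and the adhesion molecule Epcam by 1.84 ± 0.37, whose call ended without replicate 4 (adjusted p = 0.0525). The medians of the endocytic and the junction lists were -0.54 and -0.61 in pairs 1 and 2, and -1.01 and -0.99 in pairs 3 and 4.

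Endoderm transcription factors did not pass as a set (median -0.93, camera adjusted p = 0.11; adjusted p = 0.711 with an estimated correlation). Of 18 tested, 5 fell and 2 rose (7 and 3 adjusted over the list alone). Hnf4a, a regulator of serum protein genes, fell by 1.61 ± 0.35, Foxa3 by 1.61 ± 0.26, Foxa2 by 1.59 ± 0.27, Creb3l3 by 1.59 and Nr2f6 by 1.25. Sox17, which blood and endothelial cells of the embryo also use, rose by 1.12 and Cited2 by 0.94. Without replicate 4 the calls of Hnf4a (adjusted p = 0.0538), Nr2f6 (0.0542), Cited2 (0.0792) and Sox17 (0.12) ended, and that of Sox17 also without replicate 2 (0.134) and without replicate 3 (0.0902). Nr2f6 was at -0.51 (adjusted p = 0.359) without x, s and a probe sets and at -0.88 (0.0699) as the mean of its probe sets, with no call in either. The list passed in pairs 3 and 4 (median -1.13, adjusted p = 0.021) and not in pairs 1 and 2 (median -0.18, adjusted p = 0.591). Over all pairs it passed with no filter (adjusted p = 0.0287) and with the stricter filter (median -1.59, adjusted p = 0.0124), and its adjusted p ran from 0.0099 to 0.711 over all alternatives.

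**Figure D2:**
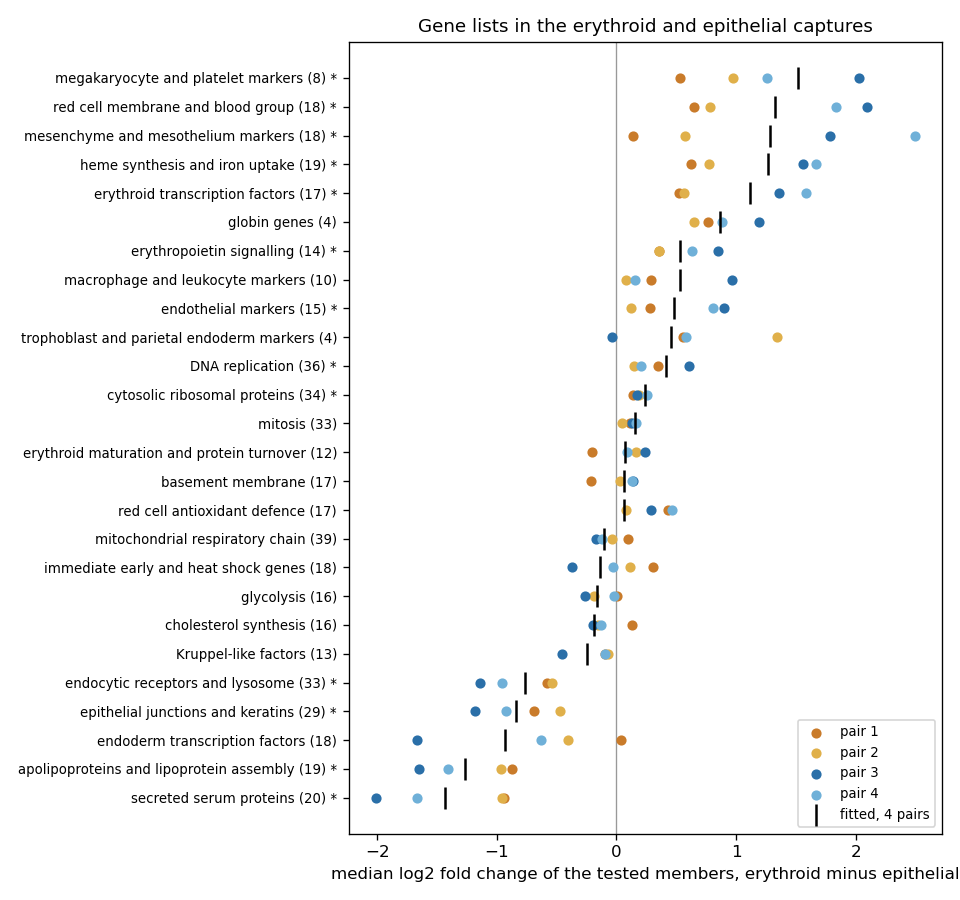
Median log2 fold change, erythroid minus epithelial, of the tested members of 26 gene lists. Coloured dots are the medians in each of the 4 pairs, black ticks the medians of the fitted values over the 4 pairs, stars mark lists with a camera adjusted p under 0.05 at the preset correlation, and the number of members tested stands in parentheses. The medians of the serum protein list (fitted -1.43) lie below 0 in all 4 pairs and those of the heme list (fitted 1.27) above 0, with pairs 3 and 4 farther from 0 than pairs 1 and 2.

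Markers of some other cell types of the yolk sac were also higher in the erythroid captures. Of 18 mesenchyme and mesothelium markers, 9 rose and 0 fell (13 and 0 adjusted over the list alone), all 18 had values above 0, and the median was 1.28 (camera adjusted p = 5.94e-06; adjusted p = 0.307 with an estimated correlation). The smooth muscle gene Tagln was higher by 1.85 ± 0.40, the mesothelial gene Upk3b by 1.69 ± 0.48 and the collagen gene Col1a1 by 1.63 ± 0.39. The call of Tagln ended without replicate 4 (adjusted p = 0.0693), and those of Upk3b and Col1a1 without replicate 3 (0.175 and 0.0962) and without replicate 4 (0.209 and 0.115). In the fit on the mean of each gene's probe sets the value of Upk3b stayed at 1.69, and only its adjusted p moved past the threshold (0.0509). The list's median was 0.34 in pairs 1 and 2 and 2.28 in pairs 3 and 4, and Col1a1 was at 0.51 and 2.68 (adjusted p of the interaction 0.00141).

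Of 8 megakaryocyte and platelet markers, 4 rose and 0 fell (5 and 0 adjusted over the list alone; median 1.52, camera adjusted p = 0.00294; adjusted p = 0.307 with an estimated correlation). These were the chemokine Pf4 at 2.16 ± 0.34, the platelet receptor Clec1b at 2.01 ± 0.31, Rab27b at 1.66 and the transcription factor Fli1 at 1.38. The epithelial captures lay above background for Rab27b on 1 of 4 arrays, so its size is uncertain. Rab27b lost its call without replicate 3 (adjusted p = 0.0754) and without replicate 4 (0.0774). Ppbp was at 1.70 ± 0.54 (adjusted p = 0.0623), and passed without replicate 1 (0.0102). Of 15 endothelial markers, the angiopoietin receptor Tek rose, by 1.35, and 0 fell (3 and 0 adjusted over the list alone; median 0.48, camera adjusted p = 0.00183; adjusted p = 0.327 with an estimated correlation). Tek lost its call without replicate 3 (adjusted p = 0.0564) and without replicate 4 (0.0855). The platelet and endothelial lists passed in pairs 3 and 4 (medians 2.03 and 0.91) and not in pairs 1 and 2 (medians 0.99 and 0.29, adjusted p = 0.0558 and 0.0859).

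Leukocyte markers did not pass as a set (10 tested, median 0.53, camera adjusted p = 0.209; adjusted p = 0.441 with an estimated correlation): Laptm5 rose by 1.55, while Lcp1, an actin bundling protein, fell, with mean signals of 435 and 1295, and Fcgr3 fell by 1.23 (1 higher and 2 lower adjusted over the list alone). The call of Fcgr3 ended without replicate 4 (adjusted p = 0.0537). The list's median was 0.35 in pairs 1 and 2 and 1.04 in pairs 3 and 4, where it passed (adjusted p = 0.0346). It also passed without replicate 4 (adjusted p = 0.0214), within a range of 0.00469 to 0.926 over all alternatives. Of 4 trophoblast and parietal endoderm markers, Tfap2c rose by 1.67 (1 higher and 0 lower adjusted over the list alone; median 0.45, camera adjusted p = 0.11), with no call without replicate 4 (adjusted p = 0.0578). On the arrays of pairs 3 and 4 Tfap2c lay under background (3.79 to 6.01 against levels of 6.39 to 6.77), so its size is uncertain. That list passed in pairs 1 and 2 (median 0.97, adjusted p = 0.00307) and without replicate 3 (adjusted p = 0.0337), was at -0.19 in pairs 3 and 4, and ranged in adjusted p from 0.00307 to 0.948 over all alternatives. On the members of the main fit its medians were 0.56, 1.34, -0.04 and 0.58 in pairs 1 to 4.

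Genes of DNA replication were slightly higher in the erythroid captures, with 4 of 36 called and 0 lower, also adjusted over the list alone (median 0.41, camera adjusted p = 0.00128; adjusted p = 0.307 with an estimated correlation). They were the sliding clamp Pcna at 0.98 ± 0.14, Rrm1 at 0.94 ± 0.23, Cdc6 at 0.86 and Rfc4 at 0.82. In the separate fits the median was 0.07 in pairs 1 and 2, where the list was not called (adjusted p = 0.0777), and 0.38 in pairs 3 and 4. On the members of the main fit the medians were 0.35, 0.15, 0.61 and 0.21 in pairs 1 to 4. Without replicate 4 the calls of Rrm1 (adjusted p = 0.123), Cdc6 (0.0999) and Rfc4 (0.061) ended, as did those of Rrm1 (0.0965) and Cdc6 (0.058) without replicate 3 and that of Cdc6 (0.0576) without replicate 2. With median centring the list's median was 0.19, 1 gene was called, and Rrm1 (0.0537), Cdc6 (0.0741) and Rfc4 (0.106) lost their calls.

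The mitosis list did not pass (33 tested, median 0.15 and -0.05 with median centring, camera adjusted p = 0.11). Of its genes 3 rose and 0 fell (1 and 0 adjusted over the list alone): Cdc25b by 1.37, the proliferation marker Mki67 by 1.04 ± 0.19 and Top2a by 0.64. Without replicate 3 and without replicate 4 the calls of Cdc25b (adjusted p = 0.158 and 0.246) and Top2a (0.172 and 0.153) ended, and that of Top2a ended without replicate 1 (0.0879) and with median centring (0.288). Of 34 cytosolic ribosomal protein genes, 8 rose and 0 fell (13 and 0 adjusted over the list alone; median 0.24, camera adjusted p = 0.00144; adjusted p = 0.307 with an estimated correlation), at medians of 0.15 in pairs 1 and 2 and 0.22 in pairs 3 and 4. Rps15 was at 0.84 ± 0.20, with no call without replicate 3 (adjusted p = 0.102) or without replicate 4 (0.0927), and Rps9 at 0.71 ± 0.14, with 2 other tested probe sets not called. Without x, s and a probe sets neither was called (Rps9 0.52, adjusted p = 0.374; Rps15 0.88, adjusted p = 0.0907), and the mean of its probe sets ended the call of Rps15 (0.0577). With median centring 0 ribosomal genes were called and the list still passed (adjusted p = 0.00418).

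Metabolic and structural lists did not pass with camera. Each passed the fry test for changes in either direction (adjusted p = 0.00627 to 0.0448). Every list but the endothelial one passed that test, so it does not set these lists apart. Among 16 glycolysis genes the hexokinases Hk1 and Hk2 rose by 1.41 and 1.06 and the glucose transporter Slc2a3 fell by 0.70 (2 higher and 1 lower adjusted over the list alone; median -0.16, mean 0.06, camera adjusted p = 0.765). Among 16 genes of cholesterol synthesis, Idi1 rose by 1.35 ± 0.26 and Sqle by 1.18, and 0 fell, also adjusted over the list alone (median -0.19, camera adjusted p = 0.765). Among 39 genes of the respiratory chain, Ndufs3 rose by 0.75 and Atp5a1 fell by 0.33 (0 and 0 adjusted over the list alone; median -0.10, camera adjusted p = 0.729). Of 17 basement membrane genes, Agrn fell by 2.10 ± 0.23 and Nid1 rose by 1.40 (1 and 1 adjusted over the list alone; median 0.06 and -0.08 with median centring, camera adjusted p = 0.765), and fry gave that list the opposite sign. Of 18 immediate early and heat shock genes, Dusp1 rose by 1.41 ± 0.24 and Hspa1b fell by 1.47 ± 0.25, with no call without x, s and a probe sets (-1.09, adjusted p = 0.0614) (2 and 2 adjusted over the list alone; median -0.13, mean 0.05, camera adjusted p = 0.817). Calls that ended without replicate 3 and without replicate 4 were those of Hk1 (adjusted p = 0.151 and 0.186), Hk2 (0.111 and 0.153), Sqle (0.0721 and 0.0945), Nid1 (0.111 and 0.149) and Atp5a1 (0.123 and 0.177). Leaving out replicate 1 ended the calls of Hk2 (adjusted p = 0.147), Ndufs3 (0.0977) and Atp5a1 (0.0548), replicate 2 those of Nid1 (0.0711), Ndufs3 (0.062) and Atp5a1 (0.0847), and replicate 4 that of Ndufs3 (0.0836). Median centring ended those of Slc2a3 (0.0564), Ndufs3 (0.213) and Atp5a1 (0.372).

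Several of the largest changes were in genes outside the lists. By the rule for naming them, these genes had 1 sign in all 4 pairs. Higher in the erythroid captures were the phosphatase Ptp4a3 by 2.57 ± 0.42, Chac2, an enzyme of glutathione breakdown, by 2.52 ± 0.29, the potassium channel Kcnn4 by 2.49 ± 0.33, Gas1 by 2.46 ± 0.40, Cldn13 by 2.35 ± 0.54, Tlcd4 by 2.29 ± 0.29 and the sialyltransferase St3gal6 by 2.26 ± 0.33. Lower were Tnfrsf12a at -2.46, Enpp3 at -2.39, Bhmt2 at -2.38, the kinase Mapk13 at -2.31, Galm at -2.28, Mfsd6 at -2.20, Tex264 at -2.15 and Cyba at -2.11. Sizes varied between pairs, for example from 0.75 to 3.85 for Ptp4a3 and from -3.76 to -0.30 for Mfsd6. The lower group lay above background on 1 of 4 arrays for Gas1, Cldn13, Tnfrsf12a, Mapk13 and Mfsd6, so the sizes of these changes are uncertain. Galm lost its call when only probe sets specific to 1 transcript were kept (-0.62, adjusted p = 0.132). Without replicate 4 the calls of Cldn13 (adjusted p = 0.0653), Mapk13 (0.0581) and Mfsd6 (0.0747) ended, and that of Mfsd6 ended without replicate 2 (0.105) and without replicate 3 (0.119).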

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

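The count over the 35 splits without the pair term and the test of RNA of the other cell type in pairs 1 and 2 were planned before their results were seen, and the other tests in this part were chosen after the results were seen.

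Without the pair term, 2 of the 35 splits of the 8 arrays into 4 and 4 gave as many calls as the split by cell type, which gave 445, so chance cannot be excluded by this count. The other split put pairs 1 and 2 against pairs 3 and 4 and gave 1347 calls, which points to a structure of the samples, and the next highest gave 0. With the pair term the real split gave 1590 calls. Of the 8 splits that part all 4 pairs, 1, the real one, gave as many and the highest other gave 0, and 8 splits are too few for a share under 5%. The other 24 splits that could be fitted part 2 pairs, so their contrast rests on 2 pairs. The highest count among them was 944, in the 2 splits that set erythroid against epithelial captures within pairs 3 and 4. That is the real contrast in those pairs, and the rest of the 24 gave 0.

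Hbb-bh1, Hbb-y, Afp and Ttr, known products of yolk sac red cells or endoderm, were near level between captures on their brightest probe sets, and 0 of the 20 brightest probe sets on the arrays were called. Because these 20 were ranked by their mean over both cell types after quantile normalisation, little difference was left to find. Their count therefore decides nothing about a ceiling. The tables argue against no explanation tested. RNA of the other cell type as the whole cause, which would give red cell globins 1 ratio within a pair, stays open. On the dimmest tested probe sets of the beta-like globins, Hba-x minus Hbb-y was 1.12 (SE 0.07) and Hba-x minus Hbb-bh1 1.46 (SE 0.17). These probe sets were as bright in erythroid captures (14.56 and 14.34) as the 100 brightest (14.29 or more), where a ceiling may give the same gap. Hba-x was at signals of 3707 to 6307 in the epithelial captures and Apoa1 at 7410 to 14665 in the erythroid captures. Both lay far above the background levels of 55.1 to 133. How much of this signal was RNA of the other cell type was not measured, and any such RNA makes fold changes smaller. A signal near the ceiling of the array stays open as a candidate explanation: the dimmest tested probe set of each gene moved farther toward the gene's own cell type than the brightest, by a median of 0.39 (Hbb-bh1 0.31, Hbb-y 0.47, Afp 0.04 and Ttr 1.29), though the gain of Afp lay within its error. For Afp the size did not follow brightness. A bright probe set, at 13.5 to 14.9 on the arrays, gave -0.86 ± 0.09 (limma adjusted p = 0.00102), and the dimmest gave -0.20 ± 0.26 (0.661). With the deposited scaling the 4 genes were at 0.08, 0.22, 0.02 and -0.03 and were not called, nor were they with arrays centred on the median or the 75th percentile, and a real lack of difference was not tested.

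The contrast between captures was smaller in pairs 1 and 2 than in pairs 3 and 4, with a median ratio of 0.601 over the 1590 calls. More RNA of the other cell type in pairs 1 and 2 may be part of it but cannot be decided: red cell genes in the epithelial captures were higher there by 0.16 (0.05 to 0.27 between single arrays), while endoderm genes in the erythroid captures were at -0.12 (-0.38 to 0.14). Each cell type's own genes were lower in pairs 1 and 2, at -0.80 for red cell genes in erythroid and -0.68 for endoderm genes in epithelial captures. Shorter RNA or weaker amplification cannot be told apart from other differences between these pairs: the lowest Gapdh 3' to 5' ratio of pairs 1 and 2 was 2.22 times the highest of pairs 3 and 4 (Actb 3.44), and both split the same arrays. A biological difference between the yolk sacs of the pairs was not tested.

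The mesenchyme, platelet and endothelial lists were called higher in the erythroid captures with camera at the preset correlation. With an estimated correlation camera did not call them (adjusted p = 0.307, 0.307 and 0.327), and the platelet and endothelial lists were not called in pairs 1 and 2. The tables argue against no explanation tested: a smaller share of epithelial RNA alone would raise every other cell type alike, and the mean of the mesenchyme list exceeded that of the leukocyte list by 0.91 (SE 0.40), but by 0.51 (SE 0.36, above 0 in 3 of 4 pairs) without Lcp1 and Fcgr3, which were higher in epithelial captures. It exceeded that of the endothelial list by 0.61 (SE 0.24), with pair 1 near 0, so this explanation stays open. Erythroid cells were captured with 2 to 3 laser pulses each and epithelial cells with 1, a difference that cannot be told apart from cell type here. Neighbouring mesenchymal cells in the erythroid captures remain an undecided candidate source, since all 18 tested genes of that list were already above 0: the 5 brightest had a median of 1.26 (SE over pairs 0.51; 0.10, 0.27, 1.79 and 2.09 in pairs 1 to 4), with Col3a1 at 1.34, Vim at 1.16, Acta2 at 1.41, Ahnak at 0.56 and Postn at 1.26. The calls of Col3a1 and Vim ended without replicate 3 (adjusted p = 0.185 and 0.0917) and without replicate 4 (0.187 and 0.0952), Ahnak and Postn were not called, and use of these genes by the erythroid precursors themselves was not tested.

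In 11 of 216 groups of 4 arrays (5.09%), about the 1 in 20 that chance gives, the highest or lowest array lay far from the other arrays. All values are log2 of signal plus offset. In the erythroid captures, Tlcd4 in replicate 4 was at 10.48 (others 10.81 to 10.83), Hnf4a in replicate 3 at 7.63 (9.62 to 9.84), Hbb-bh1 in replicate 3 at 15.30 (15.05 to 15.09) and Hk2 in replicate 3 at 9.11 (9.97 to 10.02). In the epithelial captures, Ptp4a3 in replicate 1 was at 3.78 (others 7.70 to 7.87), Trim10 in replicate 2 at 7.92 (8.58 to 8.62), Gata1 in replicate 3 at 7.43 (8.28 to 8.45) and Epor in replicate 3 at 4.74 (6.81 to 7.11). There, Afp in replicate 4 was at 14.16 (14.73 to 14.80), Ttr in replicate 3 at 14.99 (14.79 to 14.81) and Klf10 in replicate 4 at 9.19 (9.50 to 9.54).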

How the results depend on the processing

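The fits of pairs 1 and 2 and of pairs 3 and 4 were chosen after seeing the data, and the other alternatives before. The main counts were 709 probe sets higher and 881 lower. They were 160 and 285 with no replicate block, 179 and 339 without a variance trend, 376 and 520 without x, s and a probe sets (7153 tested) and 396 and 580 at 2-fold or more. With arrays centred on the median, 455 were higher. Pairs 1 and 2 alone gave 544 lower, and pairs 3 and 4 alone 1379 higher and 1445 lower. Leaving out each replicate gave 214 to 717 higher and 342 to 844 lower, both lowest without replicate 4. Of the 1590 calls, 445 were also called with no replicate block, 505 without a variance trend, 547 without replicate 4, 790 in pairs 1 and 2 and 1440 in pairs 3 and 4, and 0 were called in the opposite direction in any setting. The cause of these differences was not tested, except that fewer probe sets or pairs enter some fits.

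Gene lists called were 9 higher and 4 lower, against 0 and 0 with an estimated correlation, 5 higher and the same 4 lower with the directional fry test, and 7 to 11 higher and 4 to 5 lower in the refits. Of the 9 called higher, fry also called the heme and the ribosomal list and not the other 7 (adjusted p = 0.0754 to 0.139), and it called the globin (0.0271), antioxidant (0.00867) and trophoblast (0.0271) lists, which camera did not. The mixed fry test, for changes in either direction, passed for every list but the endothelial one (adjusted p = 0.0536), among them lists that camera did not call, such as glycolysis (0.0109), basement membrane (0.00627) and cholesterol synthesis (0.0212). Every list called with the block was also called without it, and red cell antioxidant defence was called without it (adjusted p = 0.0222) and not with it (0.105). The platelet and endothelial lists lost their calls with the stricter filter (adjusted p = 0.131 and 0.139), and the trophoblast list had no tested member there. In pairs 1 and 2 the DNA replication (0.0777), endothelial (0.0859), erythropoietin (0.216) and platelet (0.0558) lists lost theirs. Over 105 named genes, the calls of 68 ended in at least 1 setting: 49 with no replicate block, 48 without a variance trend, 37 without replicate 4, 30 in pairs 1 and 2 and 24 without replicate 3. Values past the threshold in neither setting were taken to have no direction to reverse. Atp5a1 changed sign, to 0.13 (adjusted p = 0.652), on another probe set when x, s and a probe sets were left out. The background level averaged 6.68 and was 6.38 at the 90th and 7.25 at the 99th percentile; signal near it limits what dim probe sets can show. The Gapdh difference between cell types was 0.28 on the 3' to 5' ratio and -0.35 on the 3' to middle ratio.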

Other observations

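The values in this part were picked after the data were seen, and no explanation for them was tested.

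Sex-linked genes differed between pairs, and Xist also within pair 3, while neither Xist (adjusted p = 0.341) nor Eif2s3y (adjusted p = 0.536) passed between cell types. The signal of Xist, the RNA made from the inactive X chromosome of females, was lowest in pair 3, at 612 in the erythroid and 40.6 in the epithelial capture, against 2276 to 9459 in the other pairs. The Y-linked gene Eif2s3y was highest in pair 3, at 1198 and 1813, and lowest in pair 4, at 260 and 361. On the other tested probe set of Xist, the erythroid capture of pair 3 was at 337 and the epithelial one at 14.2. For Xist the 2 captures of pair 3 were therefore unlike, so this check leaves the pairing of pair 3 uncertain. Each replicate pooled 2 to 4 yolk sacs.

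The first principal component of the tested probe sets held 39.0% of the variance and the next 26.6%. The first parted the arrays of pairs 1 and 2 (-49.2 to -22.5) from those of pairs 3 and 4 (7.74 to 62.8). The next parted the erythroid captures (0.19 to 63.9) from the epithelial captures (-36.6 to -18.3).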
